A study of Mus musculus with 5 samples.

How the data were processed

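Single-cell RNA of cells sorted as SMARTA cells was measured in 5 libraries, 1 per group. SMARTA cells are CD4 T cells that carry a transgenic T cell receptor, and per the labels' protocols CD4+CD45.1+ cells were sorted by flow cytometry and loaded on a droplet platform that reads the 3′ ends of transcripts with unique molecular identifiers (UMIs). The naive library came from spleen. The other 4 libraries came from the tumor-side inguinal lymph node on day 8 after tumor injection. The growth protocol names MC38 and the treatment protocol PyMG as the injected tumor, so which was used is unclear. The series text mentions an isotype antibody that no library's labels give, and the library called untreated here follows its title alone. Per the labels' protocols, diphtheria toxin was given on days 0 and 2 to deplete regulatory T cells (Tregs), and anti-CTLA4 antibody on days 0, 2 and 5.

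The deposited tables hold UMI counts per gene and cell, 1 table per library, with 11924 genes in each. Per the submitters' processing notes, the authors used bcl2fastq 2.20, Cell Ranger 6.0.0 with the mm10 genome, R 4.1.1 and Seurat 4.0.4. All values tested as whole numbers from 0 up, and 11809 of the gene names were found in GENCODE M21 (GRCm38), which gave the coordinates. No gene in the tables had a UMI in more than 87.5% of all 20149 cells, and none in fewer than 5 cells. Of the genes looked up, 0 of 6 housekeeping genes, 0 of 6 CD3 and receptor constant genes and 3 of 89 ribosomal protein genes are among the rows of the tables used here, so that totals and shares of UMIs refer to the listed genes alone. Genes that are not listed were not analysed here. Of the 455 genes in the fixed lists 410 are listed, and of the 97 cell type markers 64.

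Cells needed at least 200 genes and at most 10% mitochondrial UMIs, over the 5 listed mitochondrial genes; this removed 0 cells. UMIs were summed over the cells of each library and scaled by the library's total to CPM. A single UMI corresponded to 0.0726 CPM in the naive library, 0.261 in the untreated tumor library, 0.0358 in the antibody library, 0.0619 in the Treg-depleted library and 0.0593 in the library with both treatments. A gene at 0 UMIs was set to 3 UMIs, which is 0.218, 0.784, 0.107, 0.186 and 0.178 CPM in the same order, and its fold is given as "at least". Ratios carry an exact 95% interval from the conditional binomial (Clopper-Pearson) distribution, CPM values an exact Poisson interval and shares of cells an exact binomial one. All intervals cover counting error only. With 1 library per group there is no replicate check, and no test between groups was made.

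Gene counts used genes with a mean of at least 25 CPM and at least 30 UMIs over both libraries of a comparison. They give the genes at least 2-fold higher or lower. Members of gene lists were counted as higher or lower from 1.5-fold. A list's median log2 ratio, taken with zero-count members at their bound, was placed as a percentile among 10000 random lists of genes matched on mean expression in 20 bins, and its 95% interval came from 1000 Poisson draws of the counts. These percentiles describe these libraries and are no test of a treatment. A list was called shifted outside the central 95% of the random lists, a limit set after the data had been seen, and not by its member counts. On data simulated without a difference, 4.5%, 4%, 5.5%, 3.5%, 5.5% and 4% of 200 lists lay beyond this limit in the 6 comparisons, and between 94.8% and 95.7% of the intervals covered the true ratio. All simulated 3-fold differences were recovered. The counts were drawn as Poisson, the spread that the intervals assume, and the lists at random. The simulation thus checks the computation, not variation between cells or mice, or lists of genes that move together.

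Shares of cells were taken after each cell had been thinned at random to 1000 UMIs, the largest multiple of 500 that 80% of the cells of every library reached. Cells below that depth were left out: 130 naive, 22 untreated, 0 antibody, 35 Treg-depleted and 384 with both treatments. A cell counted as G2M-positive with at least 2 genes of the G2M list. Clusters came from 2000 variable genes, 30 principal components, 15 neighbours and a resolution of 0.6, over all libraries together and without batch correction. They served to find cells that are not T cells and to say where cells without Foxp3 or Il2ra, or some of the named genes, lay. A cluster mostly of 1 library may therefore reflect that library. Cells that are not T cells numbered 26, 2, 51, 19 and 15, in the same order as above, and gave the background for the shares.

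The gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. In each comparison the rule names the 12 highest and 12 lowest genes by the interval bound nearest to 1, without mitochondrial, ribosomal, sex-linked, receptor variable, immunoglobulin and hemoglobin genes and unnamed models. It also names 2 to 4 members with the largest log2 ratio of each list described. Last, it names Ctla4, Foxp3, Cd4, Cd3e, Cd8a, Cd44, Mki67, Ifng, Tbx21, Cxcr5, Bcl6, Pdcd1 and Ccr7 everywhere; Cd3e is not among the rows of the tables used here, and a few other genes that the rule names are not reported here. Eomes, Gzmk, Cldn10, Il21, Il2ra, Gzmb and Igkc, where they stand outside their own comparison, were chosen after their values had been seen.

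The alternatives were no cell filter, a stricter one (500 genes, 5% mitochondrial UMIs), edgeR's TMM factors, totals without mitochondrial and ribosomal genes, doublets from Scrublet left out, cells with at least 2 markers of another cell type left out, the mean CPM of single cells, G2M-positive cells left out, sums thinned to the smallest library, a CPM minimum of 100 or none, 0.5 UMIs added to every count, thinning to 500 UMIs or none, and at least 3 G2M genes. After the data had been seen, a pair was added: leaving out cells with a UMI of Foxp3 or Il2ra, and keeping only cells with a UMI of Trbv13-1 or Trav14d-3-dv8, the variable genes of the SMARTA receptor. A cell without a UMI of Foxp3 or Il2ra can also be one too shallow to show it. Leaving out cells with either gene also removed most of cluster 10, where 8 cycling markers were each seen in at least 25% of cells. Of that cluster 39 of 944 cells stayed with both treatments and 20 of 645 with Treg depletion. Of cluster 6, with as many such markers, 1052 of 1087 cells stayed with antibody. Cell cycle values in that set thus also reflect the choice of cells. The receptor variable gene cells still include Foxp3-positive ones, so they are not SMARTA cells cleared of Tregs. Before thinning 21.6% of Foxp3-positive cells with Treg depletion and 18.8% with both treatments held such a UMI. Alternatives used 2000 random lists. Scrublet, with an assumed rate of 0.05, called 3, 6, 1, 11 and 5 cells, which is 0.0377% of the naive library. That is too few for the tool to have worked, so doublets stayed in. The sex of the animals could not be checked, since Tsix was the only listed gene of the sex-linked list, at 71.7, 110.0, 95.5, 42.4 and 141 CPM. Shared 3′ ends were sought in the last 300 bases of each gene's transcripts with words of 31 bases.

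Computations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Random steps used fixed seeds, with the seed 1 for Scrublet and clustering.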

Results

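The data were 5 single-cell libraries of SMARTA CD4 T cells from mice, 1 library per group. Naive SMARTA cells came from spleen, and the other 4 groups from the tumor-side inguinal lymph node on day 8: untreated, anti-CTLA4 antibody, Treg depletion by diphtheria toxin, and both treatments. The naive library held 7955 cells and 13767303 UMIs, with a median of 1683 UMIs per cell. The untreated tumor library held 1099 cells, 3825958 UMIs and a median of 3133. The antibody library held 4566 cells, 27967273 UMIs and a median of 4797. The Treg-depleted library held 2186 cells, 16151098 UMIs and a median of 5208.5, and the library with both treatments 4343 cells, 16865422 UMIs and a median of 2468. The untreated tumor library, the base of 3 comparisons, was thus the smallest.

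The targets of the treatments came first. Foxp3, the lineage factor of Tregs (chromosome X, 7573644 to 7595245, plus strand), stood at 8.21 CPM in naive cells, 7.84 in untreated tumor, 4.25 with antibody, 379 with Treg depletion and 348 with both treatments. Ctla4, the inhibitory receptor that the antibody binds (chromosome 1, 60887000 to 60915832, plus strand), stood at 7.84, 134, 102, 1310.4 and 1481 CPM in the same order. The antibody acts on the protein, so the transcript is no measure of the blockade. The toxin was directed at the Tregs of the host, and both libraries from toxin-treated mice held more Foxp3 than the others. Il2ra, the high-affinity interleukin 2 receptor chain (chromosome 2, 11642807 to 11693193, plus strand), followed with 10.2, 13.1, 4.83, 577 and 584 CPM. After thinning to 1000 UMIs, Foxp3 was seen in 0.550% of 7825 naive cells, 0.836% of 1077 untreated, 0.372% of 4566 antibody, 29.7% of 2151 Treg-depleted (27.8 to 31.7%) and 20.5% of 3959 cells with both treatments (19.3 to 21.8%). Before thinning these shares were 0.905%, 1.46%, 1.18%, 58.7% and 38.0%. No cell of the clusters that are not T cells held Foxp3 at that depth, 0 of 19 in the Treg-depleted library and 0 of 15 with both treatments, which allows up to 17.6% and 21.8%. Median depth before thinning was 5303 and 2647 UMIs in all cells of these libraries and 8367 and 5762 in the cells of those clusters.

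The receptor of SMARTA cells was followed with its variable genes Trbv13-1 (chromosome 6, 41116007 to 41116468, plus strand) and Trav14d-3-dv8. Trbv13-1 stood at 169, 236, 184, 72.5 and 127 CPM in the order above. Cells were called Foxp3-positive with a Foxp3 UMI before thinning. After thinning, a UMI of either gene was seen in 29.97% of Foxp3-negative cells of untreated tumor (27.2 to 32.8%) and 25.9% with antibody (24.6 to 27.2%). In the Treg-depleted library the share was 19.3% of 879 Foxp3-negative cells (16.8 to 22.1%) and 6.45% of 1272 Foxp3-positive cells (5.16 to 7.94%). With both treatments it was 31.3% of 2354 Foxp3-negative (29.4 to 33.2%) and 6.85% of 1605 Foxp3-positive cells (5.67 to 8.20%). Before thinning these shares were 63.9%, 73.6%, 56.0%, 21.6%, 52.1% and 18.8%. Cells with a receptor variable gene, used as a set below, thus include Foxp3-positive ones in both toxin libraries. Of the cells in clusters that are not T cells, 3.92% of 51 with antibody had a UMI of either gene after thinning (0.478 to 13.5%). In the Treg-depleted and combination libraries 0 of 19 and 0 of 15 did, which allows up to 17.6% and 21.8%. Before thinning these background shares were 15.7%, 0% and 13.3%. The 18.8% of Foxp3-positive cells with both treatments before thinning is thus not far above its background of 15 cells.

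**Figure D1:**
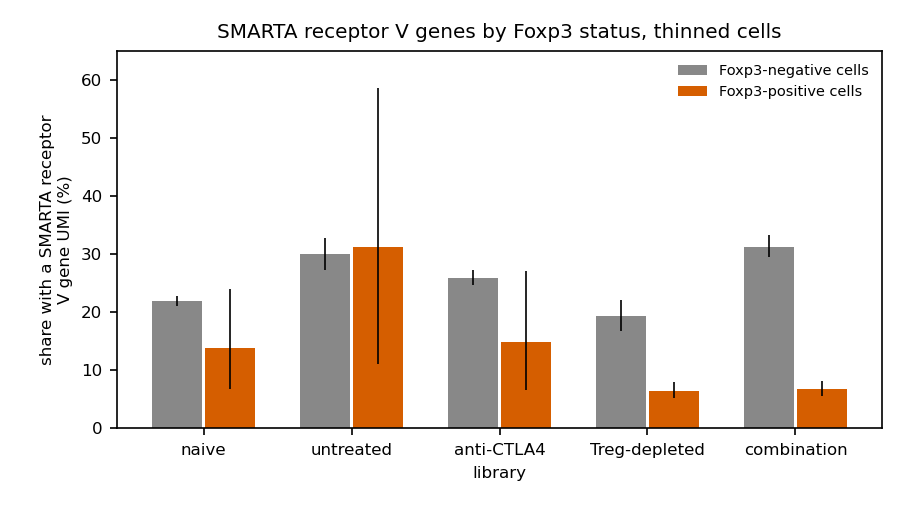
Share of thinned cells (percent, vertical axis) with a UMI of Trbv13-1 or Trav14d-3-dv8, in Foxp3-negative and Foxp3-positive cells of the 5 libraries; bars are exact 95% binomial intervals. In both toxin libraries the share in Foxp3-positive cells, 6.45% and 6.85%, lay below that in Foxp3-negative cells, 19.3% and 31.3%.

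**Figure D2:**
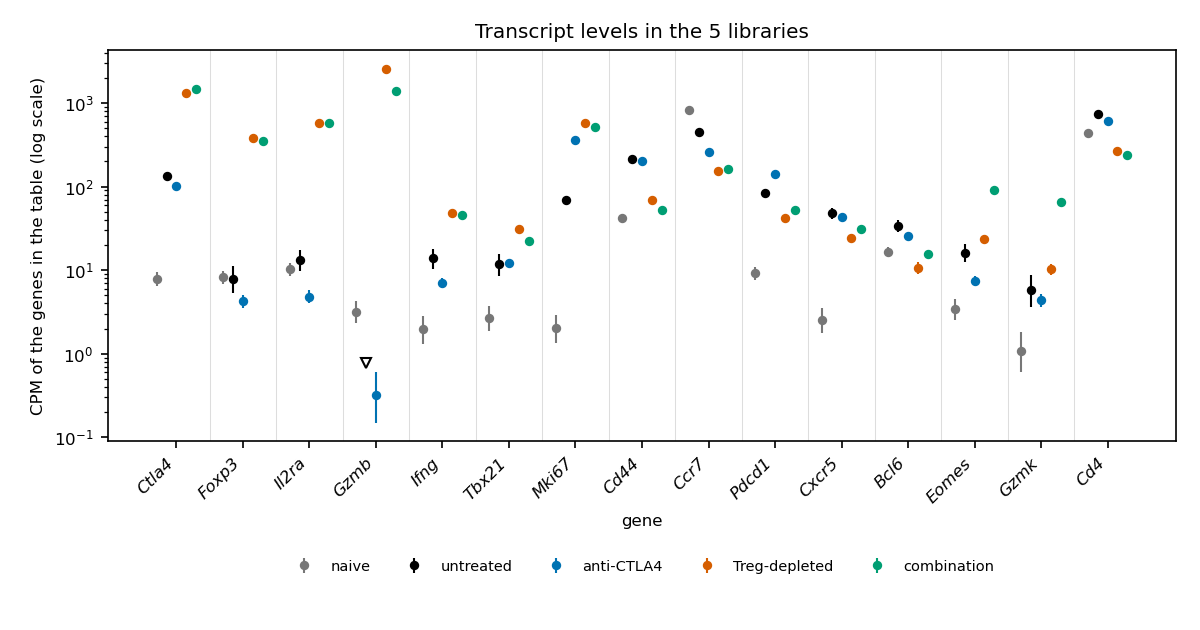
CPM (UMIs of a gene scaled by the total of its library, log axis) of 15 genes in the 5 libraries, with exact 95% Poisson intervals as bars; the open triangle marks a gene at 0 UMIs, drawn at the floor of 3 UMIs. Foxp3 stood at 379 and 348 CPM in the libraries of toxin-treated mice and at 8.21 CPM or lower in the other 3.

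How SMARTA cells of a tumor-bearing mouse differed from naive ones was addressed by the untreated tumor library against the naive library. SMARTA cells of the tumor-side lymph node held more RNA of proliferation, T follicular helper (Tfh) and T cell receptor response genes and less of naive and homing genes. Mki67, a marker of cycling cells (chromosome 7, 135689784 to 135716361, minus strand), was 33.8-fold higher (95% interval 22.8 to 51.9). Cd44, the adhesion receptor of antigen-experienced T cells, was 5.02-fold higher (4.50 to 5.59), and Ccr7, a lymph node homing receptor gene, 1.83-fold lower (1.74 to 1.93). Foxp3 was 1.05-fold lower with an interval that crossed 1 (0.695 to 1.62). Of 6814 genes with enough counts, 364 were at least 2-fold higher and 377 at least 2-fold lower.

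The gene farthest above naive cells was Wnt10a, a secreted Wnt ligand (chromosome 1, 74791516 to 74804179, plus strand), at 273 against 0.436 CPM (627-fold, 287 to 1713). Pdzk1ip1 was 230-fold higher (88.9 to 852) and Nrn1, which encodes neuritin, 59.1-fold higher (36.2 to 103). Birc5, a survival and mitosis gene, was 90.3-fold, the mitotic cyclin gene Ccnb2 59.0-fold, Ube2c 50.7-fold, Pclaf 36.7-fold, Endod1 29.0-fold and the kinesin gene Cenpe 26.8-fold higher. The G2M list had 9 of 11 measured members higher and 0 lower, with a median log2 ratio of 3.84 (3.58 to 4.14; 1.74 with the mean CPM of single cells), and the S phase list 12 of 15 higher and 0 lower, among them Tyms 5.91-fold, Hells 3.97-fold and Mcm5 2.94-fold. Bcl2a1d (37.1-fold higher) and Hist1h2ap (26.0-fold higher) share their 3′ ends with other genes, over 98.1% and 100% of their end sequence, so that their counts are uncertain. The cell cycle inhibitor list had 0 of 9 members higher and 4 lower, among them Cdkn1b (1.81-fold) and Foxo1 (1.70-fold).

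Tfh genes were higher in 13 of 17 and lower in 0 (median log2 1.15), with Tox2 23.3-fold, the follicle homing receptor gene Cxcr5 18.9-fold (13.1 to 28.0), Cd200 14.2-fold and Pdcd1, which encodes PD-1, 9.08-fold higher (7.37 to 11.3). Bcl6, the master regulator of Tfh cells, was 2.03-fold higher (1.63 to 2.53). The Treg and suppression list, which shares genes with activated T cells, had 9 of 9 higher, among them Ctla4 17.1-fold (13.8 to 21.2), Tnfrsf4 11.998-fold and Ikzf2 7.31-fold. Of 12 anergy and tolerance genes 6 were higher and 4 lower, with Izumo1r 5.40-fold higher (5.18 to 5.63) and the ubiquitin ligase gene Itch 1.98-fold lower. Inhibitory receptors were higher in 7 of 9 and lower in 1, with Lag3 21.4-fold higher (15.3 to 30.6). Receptor signalling genes were higher in 8 of 14 and lower in 1, with the activation-induced factor Irf4 11.9-fold higher (8.91 to 16.1). Co-stimulation genes were higher in 4 of 12 and lower in 2, with Icos 3.07-fold higher. The cytokine list had 3 of 5 higher and 0 lower, with Tnfsf11, which encodes RANKL, 8.96-fold higher (7.60 to 10.6). The Th1 and cytotoxic list went both ways, 3 of 11 higher and 4 lower: Bhlhe40 was 16.4-fold higher, Ccl5 17.5-fold lower (13.0 to 24.2), and Gzma, a granule protease at 54.1 CPM in naive cells, had 0 UMIs (at least 69.0-fold lower). Ccl5 was among the leading genes of cluster 3, which held 266 cells of the naive and 3 of the untreated library. Cluster 8, with Tcrg-C1, Tcrg-C2 and Tcrg-C4 among its leading genes, held 45 and 0 cells. Such cells are part of the naive values, and whether they carry the SMARTA receptor was not tested. Ifng was 7.06-fold (4.36 to 11.7) and Tbx21, the Th1 master regulator, 4.38-fold higher (2.77 to 6.95), at 13.9 and 11.8 CPM.

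Naive and homing genes were lower in 14 of 18 and higher in 1 (median log2 −1.25). Il7r, the interleukin 7 receptor gene, was 6.62-fold and Klf2 3.87-fold lower (3.71 to 4.04). Ccr9, a gut homing receptor gene, was 79.0-fold lower (33.8 to 244), and further genes far lower were Pdlim4 (18.1-fold), Tent5a (16.2-fold), Ly6c1 (13.8-fold), Actn2 (12.9-fold), Socs3 (12.5-fold) and Igfbp4 (7.22-fold). Cholesterol synthesis genes were lower in 8 of 15 and higher in 0, with Sqle 2.72-fold lower. Respiration genes were higher in 9 of 25 and lower in 0, survival genes higher in 5 of 12 and lower in 2 with Bcl2l1 2.88-fold higher, and interferon gamma response genes higher in 6 of 15 and lower in 1, with Gbp5 3.19-fold higher. Migration genes were higher in 4 of 16 and lower in 6, with Itgb1 4.11-fold higher and Itga4 6.07-fold lower. Dissociation stress genes, which rise when tissue is digested, were higher in 4 of 11 and lower in 3, with Fosb 5.57-fold and Dusp1 4.01-fold higher. Few members stood apart among type I interferon (3 of 21 higher, 0 lower), glycolysis (2 of 12 higher, 1 lower) and Myc target genes (3 of 19 higher, 0 lower), with Ifit3 2.79-fold, Tpi1 1.93-fold and Eif5a 1.72-fold higher. Rora (1.38-fold lower) and Gata3 (1.05-fold lower) were the 2 measured members of the Th2 and Th17 list. Cd4 was 1.68-fold higher, and Cd8a stood at 2.09 against 3.49 CPM with an interval that crossed 1. Spleen and lymph node differed along with naive and tumor state, so that the organ is part of this comparison. With the cells that hold 2 or more markers of another cell type left out, the Th1 median, −0.31 over all cells, was 0.70, and with TMM factors it was 0.081.

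The effect of CTLA4 blockade was addressed by the antibody library against the untreated one. Cell cycle genes stood higher, and dissociation stress, interferon gamma response and naive genes lower, with the antibody. Mki67 was 5.21-fold higher (4.61 to 5.91), Ccna2, the S and G2 phase cyclin gene, 9.08-fold (7.02 to 11.9) and the kinase gene Cdk1 6.44-fold (5.05 to 8.33). Icos, a co-stimulator on Tfh cells, was 2.70-fold (2.53 to 2.88) and Pdcd1 1.69-fold higher (1.503 to 1.90). Foxp3 was 1.84-fold lower (1.19 to 2.77) and Ctla4 1.31-fold lower (1.19 to 1.44). Of 6644 genes 176 were at least 2-fold higher and 88 at least 2-fold lower.

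All 26 measured G2M genes and all 22 S phase genes were at least 1.5-fold higher, with medians of 2.28 (2.19 to 2.39) and 1.42. Aurkb was 7.39-fold, Nusap1 6.75-fold, Ccnb1 6.79-fold, Kif22 9.14-fold, Pclaf 7.36-fold, Rrm2, a ribonucleotide reductase gene, 6.18-fold, Ube2c 5.60-fold, Tyms 4.85-fold and Tk1 4.57-fold higher. The share of G2M-positive cells after thinning was 42.8% (41.3 to 44.2%) with antibody, 19.2% (16.9 to 21.7%) in untreated tumor and 6.21% in naive cells, and before thinning 81.4%, 53.0% and 14.2%. In clusters that are not T cells, which can hold cycling cells of their own, it was 35.3% of 51 cells with antibody (22.4 to 49.9%) and 0 of 2 in untreated tumor, so that the share with antibody lay within the interval of this background. Mki67 alone was seen in 12.002% (11.1 to 13.0%) against 2.97% (2.04 to 4.17%) of cells, with 9.80% (3.26 to 21.4%) in the cells that are not T cells of the antibody library, an interval that holds its share. Median depths before thinning were 4797 and 3175 UMIs, and 5407 and 4980 in those clusters. Of 10 cell cycle inhibitors 1 was higher, Cdkn2c at 2.10-fold, and 5 lower, with Foxo3 2.41-fold lower.

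Migration and cytoskeleton genes were higher in 9 of 16 and lower in 1, with Anxa2 5.71-fold (4.94 to 6.63), S100a6 4.91-fold and S100a4 3.73-fold higher and the integrin gene Itga4 2.90-fold lower. Tfh genes were higher in 4 of 18 and lower in 1, with Maf 2.41-fold higher and Il6st 1.64-fold lower, while Bcl6 was 1.34-fold and Cxcr5 1.12-fold lower. Th1 genes were higher in 3 of 9 and lower in 2 (median 0.07, −0.03 to 0.21), with Cxcr3 1.66-fold higher and Nkg7 1.76-fold lower. Ifng was 1.98-fold lower (1.43 to 2.69), and the ratio of Tbx21 was 1.03. Glycolysis genes were higher in 3 of 13 and lower in 0, with Tpi1 2.01-fold higher, cholesterol synthesis genes higher in 4 of 14 and lower in 0, with Sqle 1.71-fold higher, and survival genes higher in 4 of 12 and lower in 1. Respiration (1 of 25 higher, Uqcr10 at 1.502-fold) and Myc target genes (2 of 19 higher, Ran at 1.68-fold) had 0 members lower. Of the Treg list 1 of 8 was higher, Tnfrsf4 at 1.72-fold, and 2 lower, with Tnfrsf9 2.56-fold lower. Jchain, the joining chain gene of plasma cells, was highest of all at 77.4-fold (26.4 to 376, from 3 UMIs in untreated tumor), along with Hist1h2ap (12.3-fold), whose 3′ end is shared, and Actg2 (6.69-fold).

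On the lower side, dissociation stress genes, which handling of the tissue also sets, were lower in 7 of 11 and higher in 0 (median −1.11), with Fos 3.90-fold (3.63 to 4.19), Dusp1 3.07-fold and Jun 2.87-fold lower. Type I interferon genes were lower in 7 of 21 and interferon gamma response genes in 7 of 15, each with 0 higher, with Ifi206 2.63-fold, Ifi209 2.34-fold, Iigp1 2.88-fold and Irf1 1.75-fold lower. Naive genes were lower in 9 of 17 and higher in 0, with Bach2, a repressor of effector genes, 3.31-fold (2.94 to 3.73), Foxp1 2.30-fold and Ccr7 1.75-fold lower; Cd44 was 1.05-fold lower. Receptor signalling genes were higher in 3 of 15 and lower in 3, with the activation marker Cd69 2.86-fold (2.75 to 2.97) and Irf8 1.76-fold lower. Anergy genes were higher in 1 of 13 and lower in 2, with Cblb 1.66-fold lower; inhibitory receptors were higher in 2 of 10 and lower in 2, with Cd160 2.70-fold higher and Nr4a3 2.18-fold and Vsir 1.56-fold lower. Co-stimulation genes were higher in 2 of 12 and lower in 3, and of 6 cytokine genes 1 was higher, Il2 at 1.60-fold with 58.1% of its 3′ end shared, and 0 lower. Nrn1 was 5.26-fold lower (4.49 to 6.15), and other genes among the lowest were Igfbp4 (4.89-fold), Atp1b1 (4.30-fold), Ifi214 (4.104-fold), Frat2 (3.14-fold), Ift80 (3.06-fold), Ppp1r15a (2.98-fold) and Dapl1 (2.43-fold). Ifi214, Ifi209 and Igfbp4 share between 54.1% and 62.2% of their ends with other genes. Rora was 2.39-fold and Gata3 1.08-fold higher, Cd4 1.20-fold lower, and Cd8a at 1.79 against 2.09 CPM not distinguishable at this depth. With G2M-positive cells left out, the counts were 49 higher and 19 lower, and the medians of the S phase, type I interferon and inhibitory receptor lists were −0.10, 0.24 and 0.065, against 1.42, −0.52 and −0.31 over all cells.

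**Figure D3:**
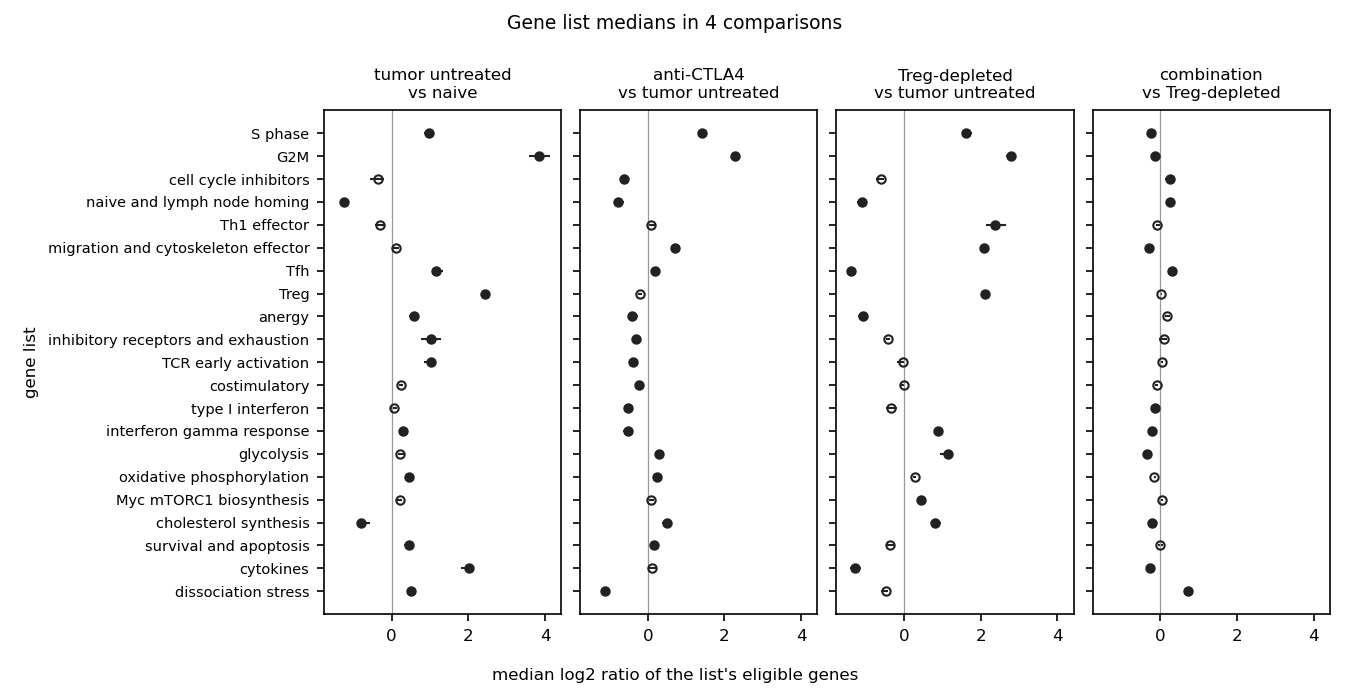
Median log2 ratio of 21 gene lists (horizontal axis) in 4 comparisons (panels), with bars for 95% intervals from Poisson draws; filled points lie outside the central 95% of matched random lists and open points within it. The G2M median was 3.84 for untreated tumor over naive, 2.28 for antibody over untreated, 2.79 for Treg depletion over untreated and −0.12 for both treatments over Treg depletion alone.

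The effect of Treg depletion was addressed by the toxin library against untreated tumor. Here Foxp3 was 48.4-fold higher (33.8 to 71.7), Il2ra 44.2-fold (33.5 to 59.5) and Ctla4 9.79-fold (8.97 to 10.7), and every gene group below was measured in this mixture of cells with and without Foxp3. Gzmb, which encodes the cytotoxic protease granzyme B (chromosome 14, 56258838 to 56262260, minus strand), stood at 2595.7 CPM against 0 UMIs (at least 3310.4-fold higher). Ifng was 3.47-fold (2.63 to 4.68), Tbx21 2.65-fold (1.95 to 3.68) and Mki67 8.45-fold higher (7.47 to 9.59). Tcf7, which encodes a transcription factor of naive and memory T cells, was 5.41-fold (5.20 to 5.64) and Bach2 9.77-fold lower (8.18 to 11.7). Of 6529 genes 456 were at least 2-fold higher and 783 lower; with cells holding Foxp3 or Il2ra left out, which kept 774 cells, the counts were 221 and 191.

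Th1 and cytotoxic genes were higher in 14 of 18 and lower in 2, with a median log2 ratio of 2.38 (2.15 to 2.65; 1.63 with cells holding 2 markers of another type left out, which made 60.1% of this library and 17.8% of untreated tumor). Among them Gzma was at least 231-fold, Plac8 105-fold (48.2 to 287) and the chemokine receptor gene Ccr2 98.7-fold higher (47.9 to 246). Klrg1, which encodes a receptor of terminal effector cells, was at least 222-fold higher. Gzmb, Klrg1, Ccr2 and Itgae were among the leading genes of cluster 9, which held 705 Treg-depleted and 0 untreated cells. Mt1, Ermn, Cdkn2a and Havcr2 were among those of cluster 10, with 645 and 0 cells. In each of these clusters 3 Treg marker genes were seen, each in at least 25% of cells. With Foxp3 or Il2ra cells left out 13 of 18 Th1 genes were higher and 0 lower (median 1.25). There Gzmb was at least 93.2-fold and Gzma at least 104-fold higher, and Ctla4 was 1.21-fold higher (1.07 to 1.37). Gzmb was seen in 49.0% of thinned cells (46.9 to 51.1%) and in 0 of 1077 untreated cells, which allows up to 0.342%; it was in 0 of 19 cells that are not T cells, and in 61.7% of cells before thinning. All 28 G2M genes were higher (median 2.79) and 22 of 23 S phase genes, with Ccna2 17.0-fold, Rrm2 13.7-fold, Aurka 12.4-fold and Cdc6 5.81-fold higher. In cells without Foxp3 or Il2ra 25 of 25 G2M genes (median 2.14) and 19 of 21 S phase genes (1.12, against 1.63) were higher. G2M-positive cells made 54.6% after thinning (52.5 to 56.7%), against 19.2% in untreated tumor, 84.9% before thinning and 21.1% of cells that are not T cells (6.05 to 45.6%). Mki67 was seen in 22.6% of thinned cells, against 5.26% in cells that are not T cells (1 of 19, 0.133 to 26.0%), so that this share lay within the interval of its background.

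The Treg and suppression list was higher in 8 of 12 and lower in 2 (median 2.12). Itgae, an integrin gene of tissue-resident cells and Tregs, was 203-fold (79.2 to 746), Tnfrsf4 6.50-fold and Tnfrsf9 4.23-fold higher. Without Foxp3 or Il2ra cells, a choice that removes Treg genes by design, the list was higher in 0 of 8 and lower in 1 (median 0.01). In receptor variable gene cells, which include Foxp3-positive ones, it was higher in 8 of 12 (1.70). Migration genes were higher in 13 of 17 and lower in 3, with Lgals3 117-fold (68.3 to 220), S100a6 45.5-fold (41.0 to 50.8), S100a4 22.1-fold and Anxa2 15.7-fold higher. Interferon gamma response genes were higher in 10 of 17 and lower in 2, with Serpina3g 67.8-fold, Gbp3 20.2-fold, Gbp7 7.99-fold and Iigp1 6.91-fold higher, and their median of 0.88 was 0.02 without Foxp3 or Il2ra cells and 0.69 in receptor variable gene cells. Type I interferon genes were higher in 4 of 21 and lower in 9, with Slfn5 3.87-fold, Slfn1 2.52-fold and Ifit1 2.35-fold lower. Glycolysis genes were higher in 12 of 17 and lower in 0, with the lactate transporter gene Slc16a3 50.6-fold, Tpi1 6.84-fold and Hk2 2.81-fold higher. Cholesterol synthesis genes were higher in 11 of 15 and lower in 0, with Mvd 4.68-fold higher, and Myc targets higher in 6 of 21 and lower in 0, with Odc1 3.49-fold higher. The Myc median of 0.44 was 0.12 without Foxp3 or Il2ra cells and 0.24 in receptor variable gene cells. The list was called shifted in neither set (percentiles 92.94 and 97.44). Its median turned to −0.0022 with cells holding markers of another type left out, and to −0.21 with G2M-positive cells left out. Respiration genes were higher in 5 of 25 and lower in 0, with Cox5a 1.84-fold higher. Cell cycle inhibitors went both ways, 4 of 12 higher and 6 lower: Cdkn2a was at least 131-fold and Cdkn1a at least 88.0-fold higher and Pik3ip1 3.70-fold lower. Further genes at 0 UMIs in untreated tumor were Ifitm1 (at least 311-fold higher), Socs2 (at least 256-fold), Mzb1 (at least 162-fold, with a shared 3′ end), Neb (at least 117-fold), Ermn (at least 89.3-fold) and Havcr2, which encodes TIM-3 (at least 86.9-fold). The metallothionein gene Mt1 was 178-fold (81.9 to 486) and the interferon-induced membrane protein gene Ifitm3 165-fold higher (107 to 271).

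Tfh genes were lower in 13 of 16 and higher in 2 (median −1.37), with Cd200 4.19-fold, Bcl6 3.19-fold, Cxcr5 1.99-fold and Pdcd1 1.95-fold lower and Maf 7.84-fold and Icos 4.83-fold higher; without Foxp3 or Il2ra cells 4 of 18 were higher and 4 lower (median 0.16), and in receptor variable gene cells 2 of 17 higher and 10 lower (−0.67). Naive genes were lower in 9 of 18 and higher in 3, with Dapl1 10.8-fold, Actn1 6.16-fold and Ccr7 2.99-fold lower; their median of −1.08 was −0.58 without Foxp3 or Il2ra cells and −0.17 (−0.34 to 0.0084) in cells with a receptor variable gene. Anergy genes were lower in 11 of 13 and higher in 1, with Egr3 2.82-fold lower, and cytokine genes lower in 4 of 6 and higher in 1, with Tnfsf11 7.15-fold, Tnfsf8 3.20-fold and Lta 2.94-fold lower. Survival genes were higher in 4 of 12 and lower in 5, and inhibitory receptors higher in 2 of 11 and lower in 5. Co-stimulation genes were higher in 4 of 12 and lower in 3, with Cd226 4.25-fold and Cd40lg, which encodes CD40 ligand, 3.32-fold lower. Over cells without Foxp3 or Il2ra anergy genes were lower in 4 of 13 and higher in 1 (median −0.26, against −1.06), cholesterol synthesis genes higher in 3 of 13 (0.21, against 0.82) and glycolysis genes in 7 of 14 (0.56, against 1.15). There the medians of migration genes, cytokine genes and inhibitory receptors, 2.08, −1.27 and −0.41 over all cells, were 0.89, −0.60 and 0.16. Receptor variable gene cells gave −0.56 for anergy, 0.54 for cholesterol synthesis, 1.02 for glycolysis, 1.82 for migration, −0.65 for cytokine and −0.43 for inhibitory receptor genes. Receptor signalling genes were higher in 4 of 15 and lower in 6, and dissociation stress genes higher in 1 of 11 and lower in 5. Among the lowest were Wnt10a (45.5-fold, 36.9 to 56.6), Tdrp (23.2-fold), Nrn1 (19.3-fold), Tgfbr3, a TGF-beta co-receptor gene (18.6-fold), Atp1b1 (15.9-fold), Ppic (11.1-fold), Ramp1 (10.5-fold), Dusp6 (9.12-fold), Zbtb20 (8.81-fold) and Itm2a (8.32-fold). Cd4 was 2.73-fold and Cd44 3.10-fold lower, Rora was 2.56-fold and Gata3 1.34-fold higher, and Cd8a stood at 0.805 against 2.09 CPM with an interval that crossed 1. The split depended on scaling: 36.8% of the genes beyond 2-fold were higher, 63.0% with TMM factors, which moved the median of all genes from −0.21 to 0.07, and 56.0% with cells holding markers of another type left out.

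**Figure D4:**
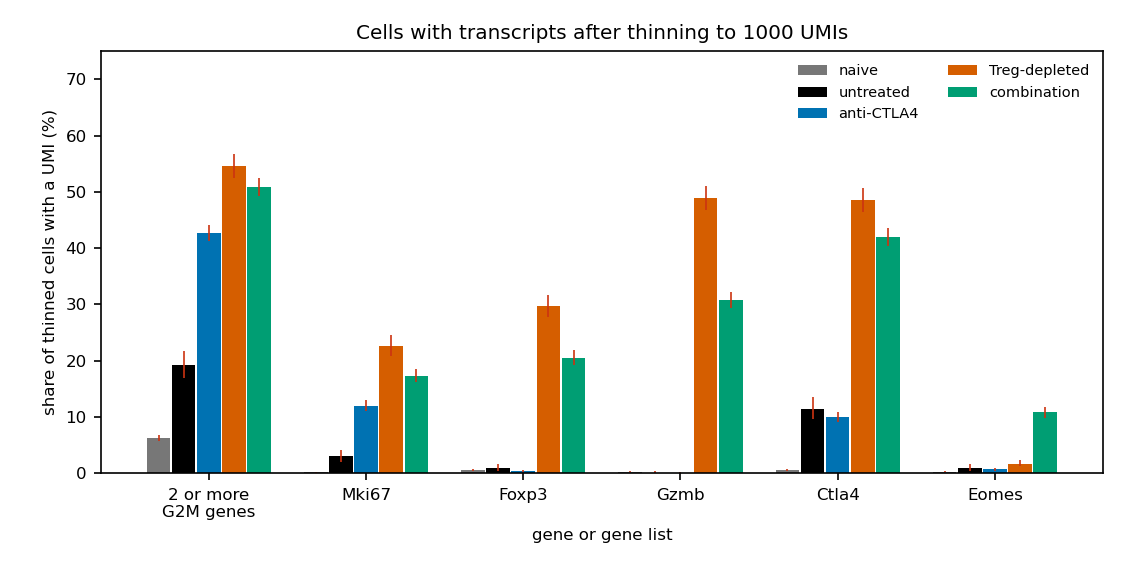
Share of cells (percent, vertical axis) with at least 2 G2M genes, or with a UMI of the gene named, after each cell was thinned to 1000 UMIs, in the 5 libraries; bars are exact 95% binomial intervals. Gzmb was seen in 49.0% of Treg-depleted cells, 30.7% of cells with both treatments and 0 of 1077 untreated cells.

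The joint effect of both treatments was addressed by the combination library against untreated tumor. In this library too Foxp3 stood far above untreated tumor: it was 44.3-fold (31.02 to 65.8), Il2ra 44.7-fold (33.9 to 60.3) and Ctla4 11.1-fold higher (10.1 to 12.1), and every group below mixes cells with and without Foxp3. Gzmb stood at 1414 CPM (at least 1803-fold higher), Ifng was 3.27-fold (2.47 to 4.40), Tbx21 1.88-fold and Mki67 7.55-fold higher (6.68 to 8.57). Of 6614 genes 409 were at least 2-fold higher and 390 lower, and without Foxp3 or Il2ra cells, over 2370 cells, 216 and 141. Different clusters held most of the latter cells, cluster 7 (led by Kcnc1, Cldn10 and Eomes) with both treatments and cluster 1 (led by Tox2, Ccr10 and Ppic) in untreated tumor. Of the 2428 cells of cluster 7, 2161 came from the combination library, and without batch correction this cluster may reflect that library.

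Th1 genes were higher in 16 of 21 and lower in 1 (median 2.51, 2.196 to 2.90), with Gzma at least 130.1-fold, Plac8 68.2-fold and Ccr2 64.0-fold higher, and Klrg1, outside that list, was at least 122-fold higher. In cells without Foxp3 or Il2ra they were higher in 11 of 17 and lower in 1 (median 1.67), and Gzmb was at least 137-fold higher. All 28 G2M genes (median 2.64) and 20 of 22 S phase genes were higher, with Ccna2 13.3-fold, Aurkb 13.2-fold and Cdk1 11.3-fold higher, and without Foxp3 or Il2ra cells 15 of 20 G2M genes (median 0.98) and 3 of 21 S phase genes with 1 lower (0.20, against 1.40) were, and in receptor variable gene cells 27 of 27 (2.30) and 15 of 21 (0.82). The Treg list was higher in 9 of 12 and lower in 2, with Itgae 147-fold higher, and its median of 1.86 was 0.09 without Foxp3 or Il2ra cells, and 1.17 with 9 of 12 higher in receptor variable gene cells. Migration genes were higher in 14 of 17 and lower in 2, with Lgals3 112-fold and S100a6 30.1-fold higher, interferon gamma response genes higher in 9 of 17 and lower in 0, with Serpina3g 75.4-fold and Gbp3 19.9-fold higher, and type I interferon genes higher in 2 of 21 and lower in 9. Glycolysis genes were higher in 8 of 15 and lower in 1, with Tpi1 5.51-fold higher, cholesterol synthesis genes higher in 8 of 14, Myc targets in 6 of 21 and respiration genes in 2 of 25, each with 0 lower, with Idi1 2.22-fold, Odc1 4.003-fold and Cox5a 1.60-fold higher. In cells that held neither Foxp3 nor Il2ra glycolysis genes were higher in 1 of 13 and lower in 1 (median 0.031, against 0.69), interferon gamma response genes higher in 3 of 16 and lower in 2 (0.15, against 0.69), and migration genes higher in 10 of 17 and lower in 2 (1.01, against 1.94). These medians were 0.33, 0.41 and 1.55 in receptor variable gene cells. Of 12 inhibitors of the cell cycle 4 were higher and 5 lower, with Cdkn2a at least 109.6-fold and Cdkn1a at least 77.7-fold higher. Socs2 (at least 211-fold), Mt1 (206-fold), Neb (at least 120.5-fold), Ermn (at least 77.8-fold), Havcr2 (at least 73.0-fold) and Mt2 (at least 72.1-fold) were also far higher. Clusters 9 and 10, whose leading genes include Gzmb, Klrg1, Mt1, Ermn and Havcr2, held 890 and 944 of the 4343 cells of this library.

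Tfh genes were lower in 12 of 17 and higher in 2, with Tox2 5.91-fold, Bcl6 2.19-fold, Pdcd1 1.57-fold and Cxcr5 1.55-fold lower and Maf 10.5-fold higher; without Foxp3 or Il2ra cells 3 of 18 were higher and 4 lower (median −0.010, against −1.09 over all cells), and in receptor variable gene cells 3 of 18 higher and 9 lower (−0.43). Naive genes were lower in 10 of 18 and higher in 3, with Dapl1 6.55-fold, Tcf7 4.43-fold (4.27 to 4.605) and Ccr7 2.84-fold lower; without Foxp3 or Il2ra cells they went both ways, 6 of 18 higher and 7 lower (median −0.26, against −1.27; −0.37 in receptor variable gene cells). Cytokine genes were lower in 4 of 6 and higher in 1 (median −1.91), with Tnfsf11 11.7-fold, Lta 4.71-fold and Tnfsf8 3.87-fold lower, and their median without Foxp3 or Il2ra cells was −2.25. Anergy genes were lower in 9 of 12 and higher in 0, with Izumo1r 2.52-fold lower, inhibitory receptors higher in 3 of 11 and lower in 6, with Lag3 3.90-fold higher and Cd200 2.70-fold lower, and survival genes higher in 3 of 12 and lower in 5. The inhibitory receptor and anergy medians of −0.63 and −0.85 were 0.46 and −0.15 when Foxp3 or Il2ra cells were left out, and those of Myc targets and cholesterol synthesis, 0.45 and 0.63, were −0.14 and −0.12; in receptor variable gene cells the 4 medians were 0.0078, −0.40, 0.16 and 0.074. Receptor signalling genes (4 of 15 higher, 6 lower) and co-stimulation genes (4 of 12 higher, 2 lower) went both ways. So did dissociation stress genes over all cells (2 of 11 higher, 1 lower). Cd40lg was 8.07-fold and Cd226 5.05-fold lower, and Icos 4.13-fold and Fosb 1.81-fold higher. The dissociation stress median of 0.12 was 0.75 without Foxp3 or Il2ra cells, with 6 of 11 higher and 0 lower. In receptor variable gene cells it was 0.55, with 5 of 11 higher and 0 lower. Far lower were Wnt10a (78.2-fold, 60.1 to 103), Ppic (25.8-fold), Bcl2a1d (17.7-fold, with a shared 3′ end), Tdrp (12.01-fold), Nrn1 (11.9-fold), Tgfbr3 (11.1-fold), Aldh2 (8.08-fold), Capn3 (7.97-fold) and Akap12 (7.76-fold). Cd44 was 4.08-fold and Cd4 3.05-fold lower, Rora 2.39-fold and Gata3 1.09-fold higher, and Cd8a at 0.830 CPM had an interval that crossed 1. Of the genes beyond 2-fold 51.2% were higher, 65.3% with TMM factors, which moved the median of all genes from −0.16 to 0.01.

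What depletion added to the antibody was addressed by the combination library against the antibody library. Gzmb was 4394-fold higher (2314 to 9610.2, from 9 UMIs), Foxp3 81.7-fold (68.1 to 98.8), Il2ra 121-fold (102 to 144) and Ctla4 14.5-fold higher (13.9 to 15.1), and every group that follows mixes cells with and without Foxp3. Ifng was 6.46-fold (5.51 to 7.59), Tbx21 1.82-fold and Mki67 1.45-fold higher (1.41 to 1.49). Of 6514 genes 265 were at least 2-fold higher and 243 lower, and without Foxp3 or Il2ra cells 386 and 268.

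Th1 genes were higher in 14 of 20 and lower in 1 (median 3.12), with Gzma 59.4-fold and Prdm1, which encodes the effector regulator Blimp-1, 26.5-fold higher. Without Foxp3 or Il2ra cells 12 of 18 Th1 genes were higher and 2 lower (median 1.81). In receptor variable gene cells 13 of 19 were higher and 1 lower (3.25). Klrg1 was at least 894-fold higher. It is among the leading genes of cluster 9, which held 890 cells with both treatments and 3 with antibody. G2M genes were higher in 6 of 28 and lower in 0 (median 0.36), with Aurka 1.85-fold higher. In cells without Foxp3 or Il2ra 27 of 27 G2M genes (median −1.39) and 21 of 22 S phase genes were lower, and Mki67 stood at a ratio of 0.348 (0.321 to 0.376). Most of those cells lay in cluster 7 with both treatments and in cluster 1 with antibody, where cluster 6 (led by Hist1h2ap, Hist1h2ae and Neil3) held most of the others. The choice removed cycling cells unevenly. It kept 39 of 944 cells of cluster 10 with both treatments and 1052 of 1087 cells of cluster 6 with antibody. In receptor variable gene cells 0 of 28 G2M genes (median −0.094) and 7 of 23 S phase genes (−0.44) were lower. Over all cells S phase genes were higher in 1 of 23 and lower in 1. Dissociation stress genes were higher in 8 of 11 and lower in 0, with Fos 5.71-fold and Fosb 4.13-fold higher, and without Foxp3 or Il2ra cells in 9 (median 1.93). Interferon gamma response genes were higher in 11 of 18 and lower in 1, with Serpina3g 57.2-fold and Iigp1 16.8-fold higher, the Treg list higher in 10 of 12 and lower in 2, with Itgae 81.3-fold higher, and migration genes higher in 14 of 17 and lower in 2, with Itga4 13.1-fold and Lgals3 9.75-fold higher. Receptor signalling genes were higher in 7 of 16 and lower in 3, with Tnfrsf9 9.15-fold higher. Co-stimulation genes were higher in 5 of 12 and lower in 2, with Cd40lg 7.68-fold lower. Naive genes were higher in 6 of 15 and lower in 5, with Il7r 2.94-fold higher and Tcf7 3.34-fold and Ccr7 1.62-fold lower. Their median of 0.11 was 0.88 without Foxp3 or Il2ra cells, with 9 of 16 higher and 1 lower. In receptor variable gene cells it was 0.77, with 9 of 15 higher and 3 lower. Mt2 (at least 527-fold), Neb (240.0-fold), Ermn (114-fold), Cdkn2a (100.2-fold), Havcr2 (69.6-fold), Socs2 (66.0-fold) and Mt1 (62.3-fold) were among the highest, while cell cycle inhibitors were higher in 2 of 11 and lower in 0.

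Tfh genes were lower in 11 of 17 and higher in 2, with Tox2 7.17-fold, Pdcd1 2.65-fold, Bcl6 1.64-fold and Cxcr5 1.38-fold lower. The Tfh median of −1.12 was −0.28 without Foxp3 or Il2ra cells, with 5 of 18 higher and 6 lower. The list was then no longer called shifted (percentile 3.6). In receptor variable gene cells the Tfh list was still shifted, at −0.65 with 2 of 18 higher and 10 lower. Cytokine genes were lower in 5 of 7 and higher in 1, with Tnfsf11 13.6-fold (11.7 to 15.8) and Il2 6.71-fold lower, and anergy genes lower in 6 of 12 and higher in 1, with Izumo1r 2.18-fold lower. Inhibitory receptors were higher in 3 of 10 and lower in 4, with Lag3 4.74-fold higher and Cd160 4.19-fold lower. Their median of −0.28 was 0.64 without Foxp3 or Il2ra cells, with 6 of 11 higher and 1 lower. In receptor variable gene cells it was 0.0091, with 4 of 10 higher and 4 lower. Survival genes were higher in 1 of 12 and lower in 4, and type I interferon genes higher in 4 of 20 and lower in 4. Metabolic lists were higher in part: 4 of 16 glycolysis genes with 1 lower, 6 of 21 Myc targets and 4 of 15 cholesterol synthesis genes with 0 lower, with Tpi1 2.74-fold, Odc1 2.58-fold and Mvd 1.80-fold higher. Over the cells without Foxp3 or Il2ra they were not: 0 of 13 glycolysis genes were higher and 3 lower (median −0.30), 1 of 19 Myc targets higher and 6 lower (−0.29), and 0 of 13 cholesterol synthesis genes higher and 6 lower (−0.55). The Treg and co-stimulation medians, 1.93 and 0.36 over all cells, were then −0.072 and −0.071, the anergy median, −0.73, was 0.29, and migration genes were higher in 7 of 17 and lower in 5 (0.26, against 1.22). Receptor variable gene cells, which include Foxp3-positive ones, kept a Treg median of 1.61 (8 of 11 higher). Their medians were −0.020 for glycolysis, 0.070 for Myc targets, −0.24 for cholesterol synthesis, 0.042 for co-stimulation, −0.16 for anergy and 0.82 for migration genes. Respiration genes (25) and the Th2 and Th17 list (3) had 0 members beyond 1.5-fold. Wnt10a was lowest at 92.4-fold (71.6 to 122), before Ppic (44.8-fold), Bcl2a1d (34.8-fold) and Hist1h2ap (21.1-fold), both with shared 3′ ends, Actg2 (19.8-fold), the interleukin 9 receptor gene Il9r (15.8-fold), Gstp1 (11.4-fold, with a shared 3′ end), Capn3 (10.9-fold), Smtn (10.5-fold), Tnfsf14 (10.2-fold) and Akap12 (10.1-fold). Cd44 was 3.89-fold, Cd4 2.55-fold and Cd8a 2.15-fold lower. With cells holding markers of another type left out the G2M median was −0.25, and 63.8% of the genes beyond 2-fold were higher, against 52.2%.

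What the antibody added to depletion was addressed by the combination library against the Treg-depleted one. Summed over all cells, 76 of 6261 genes were at least 2-fold higher and 20 lower. Foxp3 was 1.09-fold lower (1.05 to 1.13) and Ctla4 1.13-fold higher (1.11 to 1.15), but Foxp3 was seen in 20.5% against 29.7% of thinned cells, and 2370 of 4343 cells against 774 of 2186 held neither Foxp3 nor Il2ra, so that the libraries differed in the cells they held. Eomes, a regulator of cytotoxic and memory T cells (chromosome 9, 118478212 to 118486132, plus strand), was 3.87-fold higher (3.46 to 4.34), the granzyme K gene Gzmk 6.43-fold (5.46 to 7.61) and Cldn10 9.15-fold (7.35 to 11.5). Mki67 was 1.12-fold and Ifng 1.06-fold lower. Without Foxp3 or Il2ra cells 258 genes were higher and 143 lower, over cells that lay mostly in cluster 7 with both treatments, a cluster led by Eomes and Cldn10 among others, and more in cluster 1 than in any other with Treg depletion alone.

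Dissociation stress genes were higher in 6 of 11 and lower in 0 (median 0.74, 0.67 to 0.80), with Fosb 4.49-fold (4.18 to 4.83), Fos 2.83-fold, Jun 2.37-fold and Dusp1 2.31-fold higher. Th1 genes were higher in 4 of 21 and lower in 5, with the chemokine gene Ccl5 2.18-fold higher and Tbx21 1.41-fold lower. Inhibitory receptors were higher in 3 of 11 and lower in 1, with Lag3 2.65-fold higher (2.498 to 2.81) and Cd160 2.21-fold lower. Tfh genes were higher in 2 of 16 and lower in 0, with Tox, a regulator of exhausted and Tfh cells, 2.61-fold higher, Bcl6 1.46-fold, Cxcr5 1.28-fold and Pdcd1 1.24-fold. Naive genes were higher in 3 of 14 and lower in 0, with Foxp1 2.15-fold and Ccr7 1.05-fold higher, and anergy genes higher in 2 of 12 and lower in 0, with Cblb 2.07-fold higher. Sox4 (7.04-fold), Itga4 (7.19-fold), Tm6sf1 (5.65-fold), Dcp1b (5.48-fold), Tubb2b (4.27-fold), Frat2 (3.68-fold), the kinase gene Txk (3.18-fold) and Neurl3 (3.12-fold) were further genes higher with both treatments. Cytokine genes had 1 of 5 higher, Il10 at 2.06-fold, and 1 lower, Lta at 1.60-fold, and survival genes 1 of 12 higher and 1 lower, with Bcl2 1.57-fold higher.

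All 28 G2M genes stayed within 1.5-fold (median −0.12), and 1 of 23 S phase genes was lower, Cdc6 at 1.56-fold. G2M-positive cells made 50.8% (49.3 to 52.4%) of thinned cells against 54.6%, and 33.3% of the 15 cells that are not T cells (11.8 to 61.6%), an interval that holds the 50.8% of this library. Without Foxp3 or Il2ra cells 24 of 26 G2M genes (median −1.16) and 19 of 21 S phase genes were lower, and Mki67 had a ratio of 0.400 (0.363 to 0.441), between cells of different clusters as said above. That choice kept 39 of 944 cells of cycling cluster 10 with both treatments and 20 of 645 with Treg depletion. In receptor variable gene cells 0 of 28 G2M genes (median −0.27) and 10 of 23 S phase genes (−0.56) were lower. Ifitm1 was 5.74-fold (5.30 to 6.23), Ifitm3 2.88-fold (2.79 to 2.97) and Ifitm2 2.73-fold lower, while the type I interferon list had 0 of 20 members beyond 1.5-fold and the interferon gamma list 1 of 18 higher, Nlrc5 at 1.54-fold. Mzb1 (5.23-fold), Hist1h2ap (6.71-fold), Eno1 (4.59-fold) and Dynlt1f (3.15-fold), lower as well, share at least 90.7% of their 3′ ends with other genes, and Ahsa1 (2.26-fold) 76.3%. Polr2l (2.84-fold), Slpi (2.47-fold) and Hist1h2ae (2.36-fold) were lower too. Migration genes had 1 of 17 higher and 1 lower, with S100a6 1.51-fold lower, and glycolysis 0 of 17 higher and 1 lower, Eno1. Receptor signalling genes had 0 of 14 higher and co-stimulation genes 0 of 12, and Cd40lg (2.43-fold) was the 1 lower member of either. Over all cells no member was beyond 1.5-fold among 13 Treg, 11 inhibitor, 25 respiration, 21 Myc target, 15 cholesterol synthesis and 3 Th2 and Th17 genes. Among cells without Foxp3 or Il2ra glycolysis genes were lower in 7 of 14 (median −0.69, and −0.74 with 11 of 17 lower in receptor variable gene cells) and migration genes in 7 of 17, while 5 of 10 inhibitors were higher and 1 lower (0.60). Myc targets were there lower in 5 of 19 and higher in 1, cholesterol synthesis genes lower in 3 of 13 and respiration genes in 1 of 25 (median −0.44). Cd44 was 1.32-fold and Cd4 1.12-fold lower, and Cd8a had a ratio of 1.03. Of the genes beyond 2-fold 79.2% were higher, 68.1% with TMM factors, which moved the median of all genes from 0.03 to −0.08.

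Last, the combination library was set against the product of both single treatments, each taken relative to untreated tumor. The excess, on the log2 scale, was negative for all 26 G2M genes (median −2.44, −2.53 to −2.33) and all 22 S phase genes (median −1.55), with Mki67 at −2.54 and Top2a, a DNA topoisomerase gene, at −1.98: depletion and antibody each stood with higher cell cycle RNA, and together no higher than depletion alone. It was positive for 10 of 11 dissociation stress genes (median 1.85, 1.71 to 1.95), 15 of 17 naive genes (0.83), 8 of 10 cell cycle inhibitors (0.97), 12 of 12 anergy genes (0.56), 10 of 14 receptor signalling genes (0.56), 7 of 10 inhibitory receptors (0.48), 16 of 21 type I interferon genes (0.41), 11 of 15 interferon gamma response genes (0.53), 8 of 12 co-stimulation genes (0.25) and 5 of 8 Treg genes (0.26). It was negative for 14 of 14 cholesterol synthesis (−0.76), 11 of 13 glycolysis (−0.68), 13 of 16 migration (−0.91), 23 of 25 respiration (−0.37), 5 of 5 cytokine (−0.45), 8 of 12 survival (−0.18) and 11 of 19 Myc target genes (−0.07). Tfh genes lay on both sides (8 and 8, median 0.01), as did the Th1 genes counted (5 below, 4 above, median −0.07, −0.21 to 0.07). List excesses used only genes with enough counts in every comparison of a treated library with untreated tumor. Of the 28 Th1 genes this kept 9 and left out Eomes, Gzmk and Gzmb, so the Th1 excess does not cover the list as a whole. Gzmb alone, at 0 UMIs in untreated tumor, had an excess of 0.41 (−0.33 to 1.59). The Th1 excess was −1.07 with G2M-positive cells left out and 0.36 without Foxp3 or Il2ra cells. Single genes above the product were Cldn10 (5.06), Eomes (3.09), Gzmk (3.08), Il2ra (1.45), Bcl6 (0.96), Ifng (0.89, 0.43 to 1.34), Ccr7 (0.89), Foxp3 (0.76, 0.09 to 1.27), Ctla4 (0.57), Cxcr5 (0.52) and Cd4 (0.099). In receptor variable gene cells the intervals of Ctla4 (−0.12, −0.29 to 0.048), Ifng (−0.49, −1.18 to 0.040), Foxp3 (0.54, −0.25 to 1.26), Cd4 (−0.028, −0.14 to 0.084) and Pdcd1 (−0.21, −0.49 to 0.041) held 0, and without Foxp3 or Il2ra cells Cxcr5 stood at −0.086 (−0.40 to 0.24) and Ifng at 0.55 (−0.053 to 1.13). Tbx21 (−0.54), Pdcd1 (−0.44) and Cd44 (−0.33) lay below the product, and Il21, a Tfh cytokine gene, did so too (−5.61, −7.14 to −3.99, with 2 UMIs in untreated tumor). Without Foxp3 or Il2ra cells the G2M median was −3.59. With G2M-positive cells left out the excess turned to 0.31 for S phase, −0.30 for inhibitory receptor, −0.47 for type I interferon, −0.24 for interferon gamma response, −0.49 for co-stimulation and −0.69 for Treg genes, and the Treg excess was negative in 3 other settings too (−0.026 without cells holding markers of another type, −0.21 with the mean CPM of single cells, −0.10 in receptor variable gene cells). The product uses the untreated library of 1099 cells for every gene, and no replicate shows how far such an excess moves between mice.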

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

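No test was run on the differences below, before or after they were seen, since each group has 1 library. Lists were picked for antibody ratios called shifted in opposite directions without and with Treg depletion, so that this contrast is no finding. Each value is the median log2 ratio of antibody over no antibody with depletion, minus the same ratio without depletion.

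Proliferation genes gave the lowest values. The G2M list differed by −2.41, from 2.28 without depletion to −0.12 with it, and the S phase list by −1.65, from 1.42 to −0.23. With depletion all 28 G2M genes stayed within 1.5-fold. Migration genes such as S100a6 and Anxa2 differed by −0.99 (0.71 and −0.28). Cholesterol synthesis genes differed by −0.72 (0.51 and −0.22), and glycolysis genes by −0.64 (0.31 and −0.33). In the opposite sense, dissociation stress genes such as Fos, Fosb and Jun differed by 1.85, from −1.11 without depletion to 0.74 with it. Naive and homing genes differed by 1.03 (−0.76 and 0.27), and cell cycle inhibitors by 0.86 (−0.61 and 0.25). Foxp3 stood at 7.84 and 4.25 CPM in the pair without depletion and at 379 and 348 CPM in the pair with it, so that the pairs also differed in the cells they held.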

How the results depend on the processing

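The alternatives that leave out cells with Foxp3 or Il2ra, or keep only cells with a receptor variable gene, were chosen after seeing the data, and what makes a change of sign count as a reversal was tightened after a first run. Values below are median log2 ratios of the lists, counts of genes at least 2-fold higher and lower, or shares of G2M-positive cells; comparisons are named as numerator over denominator, and "excess" is the combination over the product of the single treatments. Unless said otherwise, the cause was not tested. No paired analysis was possible because each group has 1 library. The stricter cell filter, 0.5 UMIs added and totals without mitochondrial and ribosomal genes moved none of the main values. The stricter filter removed 6, 1, 0, 0 and 24 cells in the order naive, untreated, antibody, Treg-depleted and combination. Only 5 mitochondrial and 3 of 89 ribosomal protein genes are listed, so these 2 settings tested little. Scrublet called too few cells to have worked, and the cell filter removed no cell, so leaving out its doublets or omitting the filter tests nothing. A library of 1099 cells limits every comparison with untreated tumor, where a single UMI is 0.261 CPM, and the median of a list can hang on a few members.

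With TMM factors the Th1 median of untreated over naive was 0.081, for Treg-depleted over untreated 385 genes were lower with medians of 3.07 (G2M) and 2.66 (Th1), the G2M median of combination over untreated was 2.80, and the G2M excess −2.64. Of the other values 105 moved, 34 did not and 0 reversed.

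With cells holding 2 markers of another type left out, untreated over naive gave 3.403 (G2M) and 0.70 (Th1). Treg-depleted over untreated gave 271 genes higher and 213 lower, with G2M 2.35 and Th1 1.63, and the Myc median turned to −0.0022. Combination over untreated gave 183 lower and G2M 2.12, and inhibitory receptors turned to 0.045. Combination over antibody gave 161 lower, and G2M turned to −0.25, anergy to 0.061 and Myc to −0.024. Combination over Treg-depleted gave 121 higher and 35 lower. The excess was −2.79 for G2M and turned to −0.026 for the Treg list.

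With the mean CPM of single cells, G2M of untreated over naive was 1.74, and 58 genes were lower in antibody over untreated. Treg-depleted over untreated gave 439 lower and Th1 2.12, combination over untreated 197 lower, G2M 2.39 and Th1 3.16, and combination over Treg-depleted 138 higher. The excess was −2.73 for G2M and turned to −0.21 for the Treg and −0.088 for the co-stimulation list.

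Leaving out cells with 2 G2M genes removes cycling cells by construction and leaves no G2M median. Th1 of untreated over naive was −0.12. Antibody over untreated gave 49 higher, 19 lower and Th1 0.35, and turned S phase to −0.10, inhibitory receptors to 0.065 and type I interferon to 0.24. Treg-depleted over untreated gave 260 higher, 276 lower and Th1 2.68, and turned S phase to −0.21 and Myc to −0.21. Combination over untreated gave 245 higher, 172 lower and Th1 3.69, and turned S phase to −0.035, Tfh to 0.090, inhibitory receptors to 0.28, type I interferon to 0.18 and Myc to −0.43. Combination over antibody turned co-stimulation to −0.026, glycolysis to −0.045 and Myc to −0.41. Combination over Treg-depleted gave 227 higher and 103 lower, and turned S phase to 0.22. The excess was −1.07 for Th1 and turned to 0.31 for S phase, −0.69 for Treg, −0.30 for inhibitory receptors, −0.49 for co-stimulation, −0.47 for type I interferon and −0.24 for interferon gamma genes. Sums thinned to the smallest library gave Th1 0.022 for untreated over naive.

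A minimum of 100 CPM tests fewer genes: 124 higher and 116 lower for untreated over naive, 63 and 33 for antibody over untreated, 193 and 262 for Treg-depleted over untreated, 152 and 139 for combination over untreated, 100 and 82 for combination over antibody, and 25 and 12 for combination over Treg-depleted. Survival of untreated over naive turned to −0.14, G2M of antibody over untreated was 2.15, and Th1 was 1.32 for Treg-depleted and 1.21 for combination over untreated. No minimum tests more genes: in the same order 938 and 1053, 761 and 403, 1231 and 1937, 1275 and 1021, 964 and 924, and 560 and 146. Th1 was then −0.51 for untreated over naive, 1.84 for Treg-depleted and 2.19 for combination over untreated, and cytokines of Treg-depleted over untreated turned to 0.0035.

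With Foxp3 or Il2ra cells left out, G2M of antibody over untreated was 2.44. Treg-depleted over untreated gave 221 higher, 191 lower, G2M 2.14 and Th1 1.25, and turned Tfh to 0.16. Combination over untreated gave 216 higher, 141 lower, G2M 0.98 and Th1 1.67, and turned inhibitory receptors to 0.46, Myc to −0.14 and cholesterol synthesis to −0.12. Combination over antibody turned G2M to −1.39, Treg to −0.072, anergy to 0.29, co-stimulation to −0.071, glycolysis to −0.30 and Myc to −0.29. Combination over Treg-depleted gave 258 higher and 143 lower, and the excess was −3.59 for G2M and 0.36 for Th1.

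With only cells holding Trbv13-1 or Trav14d-3-dv8, Th1 of untreated over naive was 0.0049. Treg-depleted over untreated gave 463 lower, G2M 2.55 and Th1 1.79, and combination over untreated 217 lower, G2M 2.30 and Th1 2.18, with inhibitory receptors turned to 0.0078. Combination over antibody turned G2M to −0.094 and glycolysis to −0.020. Combination over Treg-depleted gave 188 higher and 44 lower, and the excess was −2.64 for G2M and turned to −0.10 for the Treg list.

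Shares of G2M-positive cells moved with depth in every library: thinned to 500 UMIs they were 2.00% naive, 8.65% untreated, 28.3% antibody, 42.5% Treg-depleted and 34.4% combination, without thinning 14.2%, 53.0%, 81.4%, 84.9% and 72.1%, and with at least 3 G2M genes 0.422%, 5.11%, 26.0%, 41.0% and 32.7%. The combination share lay above the antibody share when cells were thinned and below it without thinning.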

Other observations

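The tests on receptor genes below and the share of genes with shared ends that were lower were chosen after the result was seen. The spread of Eomes over cells was added once the first test of free RNA had left it open, but before its own result was seen; the other tests were written first. Some transcripts with no place in the comparisons stood apart in single libraries. Il21, which encodes a cytokine that Tfh cells give to B cells, stood at 19.7 CPM with the antibody (18.1 to 21.4), 0.581 in naive cells, 0.523 in untreated tumor, 1.92 with Treg depletion and 1.48 with both treatments. After thinning it was seen in 1.47% of 4566 antibody cells (1.14 to 1.86%; 7.12% before thinning) and 0 of 51 cells that are not T cells, which allows up to 6.98%, and in 0.0128%, 0%, 0.186% and 0.101% of the other libraries; 0 of 1077 untreated cells allows up to 0.342%. Median depths of the antibody library were 4797 UMIs in all cells and 5407 in those that are not T cells. Gzmb was seen in 30.7% of thinned cells with both treatments (29.3 to 32.2%) and 49.0% with Treg depletion alone.

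Transcripts of other cell types differed between libraries as well. Igkc, the kappa light chain gene of B cells, stood at 27.2 CPM in naive cells, 6.01 in untreated tumor, 367 with antibody, 3013 with Treg depletion and 1451 with both treatments, and Jchain at 1.09, 0.784, 60.7, 137 and 82.6 CPM. Cells with at least 2 markers of another type made 4.94%, 17.8%, 29.0%, 60.1% and 34.2% of the libraries, in the same order, while clusters that are not T cells held 0.327%, 0.182%, 1.12%, 0.869% and 0.345% of the cells. By type, 177, 24, 188, 944 and 1070 cells had 2 B cell markers, 91, 166, 1160, 803 and 798 had 2 dendritic cell markers, 82, 9, 146, 252 and 163 had 2 myeloid markers, and 67, 5, 44, 21 and 7 had 2 gamma-delta T cell markers. The sort on CD4 and CD45.1 should remove B cells. Deeper cells show more markers at the same level of free RNA, and activated T cells also express some of the dendritic list, so these counts are not counts of foreign cells.

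Foxp3 in the libraries of toxin-treated mice was weighed against 3 explanations. A sort that held cells without the SMARTA receptor is a candidate explanation: the share of Foxp3-positive cells with a UMI of Trbv13-1 or Trav14d-3-dv8, divided by that of Foxp3-negative cells, was at most 0.333 in these libraries. Foxp3 switched on in SMARTA cells as the whole cause is argued against, since Foxp3-positive cells held 111 UMIs of 3 other Trbv genes beside 898 of Trbv13-1, against 2 beside 904 in untreated tumor, a ratio of 55.9 (15.1 to 467). Free RNA is argued against by a Foxp3 share of 0 in 34 cells that are not T cells (up to 10.3%), against 23.9% of 6076 others, at median depths of 8055.5 and 3379 UMIs. That a part of the Foxp3-positive cells are SMARTA cells stays open, as does an effect of the depletion itself on either kind of cell, which 1 library per group leaves untested.

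Eomes, Gzmk and Cldn10, higher with both treatments than with Treg depletion alone, were weighed next. Cells without the SMARTA receptor are argued against, since 34.5% of Eomes-positive and 32.6% of Eomes-negative cells without Foxp3 or Il2ra held a receptor variable gene, a ratio of 1.06. Fewer Foxp3-positive cells in the combination library are argued against as well, since without cells holding Foxp3 or Il2ra the log2 ratios were still 1.68 for Eomes, 3.63 for Gzmk and 2.72 for Cldn10. Whether free RNA adds to it cannot be told from the 15 cells that are not T cells, of which 1 held Eomes (6.67%, 0.169 to 31.9%), but free RNA spread alike over all cells is argued against by an Eomes share of 18.4% in 2068 cells without Foxp3 or Il2ra and 2.43% in 1891 cells with either, a ratio of 7.57. A response to both treatments together stays open and untested, since each library came from 1 group and any other difference between these libraries would look the same.

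Hist1h2ap, Mzb1, Eno1 and Dynlt1f, lower with both treatments than with Treg depletion alone, share their 3′ ends with other genes. Reads shared between near-identical genes and counted otherwise in 1 library, as a shift of all such genes, are argued against: their median log2 ratio lay 0.034 above that of genes with unshared ends. The same difference with cells thinned to equal depth was 0.00328, which says nothing of depth, as there was no difference to remove. Whether it holds for a part of the genes cannot be told: 5.88% of 68 genes with shared ends were at least 2-fold lower, against 0.124% of 5658 without, but these were the 4 genes that prompted the question, and without them the count was 0 of 64. No biological explanation was tested, and the reads were not mapped again here.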
